A study of Homo sapiens with 12 samples.

How the data were processed

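HELP-tagging libraries of 6 DNA samples from 2 clear cell renal cell carcinoma lines were analysed, each digested with HpaII and with MspI in separate reactions. Per the labels' protocols, digested DNA was ligated to adapters, cut with EcoP15I to leave a short tag beside the CCGG site, transcribed in vitro, reverse transcribed and amplified in 18 cycles of PCR, with no molecular identifier described. The deposited files hold, for each library, the expected count of tags at every CCGG site with a tag, on the left and right of the site and as their sum. Counts were not normalized by the authors as far as the files show, since each file states a total that its counts add up to, and these totals differ between libraries. Between 8.23% and 11.5% of the listed sites of a library had counts that were not whole (tolerance 1e-06), as counts split over several places of alignment would give. The coordinates are those of hg19, per the submitters' processing notes. The aligner is not given in the sources used here.

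Totals ran from 189704 to 12442031 tags per library. Joined on site number, 1019951 sites had a tag in at least 1 library, of which 996035 lie on chromosomes 1 to 22 and X and were used for bins and site classes. Tags on the mitochondrial genome, on unplaced contigs and on the decoy sequence stayed out of the bins. Within a line the 2 AA libraries of an enzyme shared between 67.5% and 79.5% of the sites of the smaller list, so no pair was 1 library deposited in duplicate.

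Site counts were summed in bins of 100 kb from position 1 of each chromosome and rounded to whole numbers. Of 28380 bins with a listed site, 15623 had at least 10 MspI tags in each of the 6 MspI libraries and at least 10 HpaII tags over the 6 HpaII libraries, and were tested. edgeR 4.0.16 (R 4.3.3) fitted a quasi-likelihood model over all 12 libraries with terms for the DNA sample, the enzyme, the enzyme by cell line and the enzyme by treatment, so that coefficients are differences of HpaII relative to MspI. A second fit had a treatment term for each line and gave their difference. TMM factors were computed within each enzyme, p-values were adjusted by the Benjamini-Hochberg method, and a bin was called at an adjusted p under 0.05. With 1 control per line the spread is pooled over lines, with 3 residual degrees of freedom in the first fit and 2 in the second, so a single control is assumed to vary like the other samples. The first fit was tested on simulated data with 200 bins changed 8-fold by AA in both lines among 11645 bins. It recovered 43.5% of them, and 8 of its 95 calls were false. The changed bins were drawn from those with higher mean HpaII counts, and no control library was given a bias. These rates therefore do not carry over to bins with few tags in a control.

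Bins were named by a rule fixed before the data were examined. The 5 largest rises and the 5 largest falls past the threshold were named where every AA sample moved in the same direction from the control of its line, or, between lines, where the 3 samples of each did not overlap. Where fewer passed, those with the smallest p followed, given by their values. The ratio given per bin is the library's share of HpaII tags in the bin over its share of MspI tags, out of all tested bins, so 1 is the genome-wide mean. Folds against samples with 0 tags use a floor of 3 tags per library, and a ratio to 1 to 3 tags has an exact Poisson interval at 95%.

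The number of reference CCGG sites in a 1 kb window around a site was taken from the running site numbers in the files, between the first and last listed site of the window, and is therefore a lower bound. Tags were summed in classes of 1 to 2, 3 to 7, 8 to 15 and 16 or more sites. Tested on simulated data with a 3-fold rise at isolated sites of the 769 AA libraries over 996035 sites, the sparse-to-dense fold came out as 2.99. The treatment labels were permuted exactly within lines. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for sites, classes and figures.

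The analysis had been planned for promoters, with 16 gene lists fixed in advance. No gene annotation of the build of these files was used here, and the annotation at hand is of another build, so promoters, gene lists and gene names were not analysed and the planned bins took their place. The fits per line, their difference and the MspI background had been planned for promoters and were moved to bins. The labels give the 2 AA samples of each line the numbers 1 and 2 without saying what they pair.

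Alternatives were library totals without TMM, TMM over all 12 libraries, DESeq2 1.42.0, no low count filter, at least 10 HpaII tags in every library, thinning to the smallest library of each enzyme, HpaII alone, a replicate block, no cell line or treatment term, bins of 1 Mb, and leaving out each DNA sample in turn. For copy number, MspI tags were summed in 1 Mb bins with at least 20 tags in each MspI library and 100 reference sites and fitted with terms for line and treatment in edgeR. Called bins on autosomes at most 3 uncalled bins apart were joined into segments of at least 10 called bins.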

Results

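Cytosine methylation was read with HELP-tagging in 2 clear cell renal cell carcinoma lines, labelled 769 and 786, with and without ascorbic acid (AA), a cofactor of the TET enzymes that oxidise 5-methylcytosine. HpaII cuts the sequence CCGG only when its inner cytosine carries neither 5-methylcytosine nor 5-hydroxymethylcytosine, while MspI cuts it in either state, so a high HpaII signal relative to MspI reads a lack of modification. Each line had 1 control and 2 AA-treated DNA samples, and each DNA sample had 1 HpaII and 1 MspI library, which makes 12 libraries from 6 DNA samples. The labels number the 2 AA samples of a line without saying whether they are separate cultures, doses or times. They are called replicates here, and each SD and p-value measures the spread between these samples, whatever its source.

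The MspI libraries held between 3785890 and 12442031 tags at 314244 to 613191 CCGG sites. The HpaII libraries of 769 held 5734607 tags in the control, 6922795 in AA replicate 1 and 3111094 in AA replicate 2, at 107494, 279974 and 136539 sites. Those of 786 held 189704 tags in the control, 11054037 in AA replicate 1 and 4012468 in AA replicate 2, at 35497, 269035 and 286374 sites. The 786 control HpaII library was the shallowest of the 12, and every AA effect in 786 was measured against it. Tags were amplified by PCR without molecular identifiers, so intervals and floors given here cover counting error only.

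**Figure D1:**
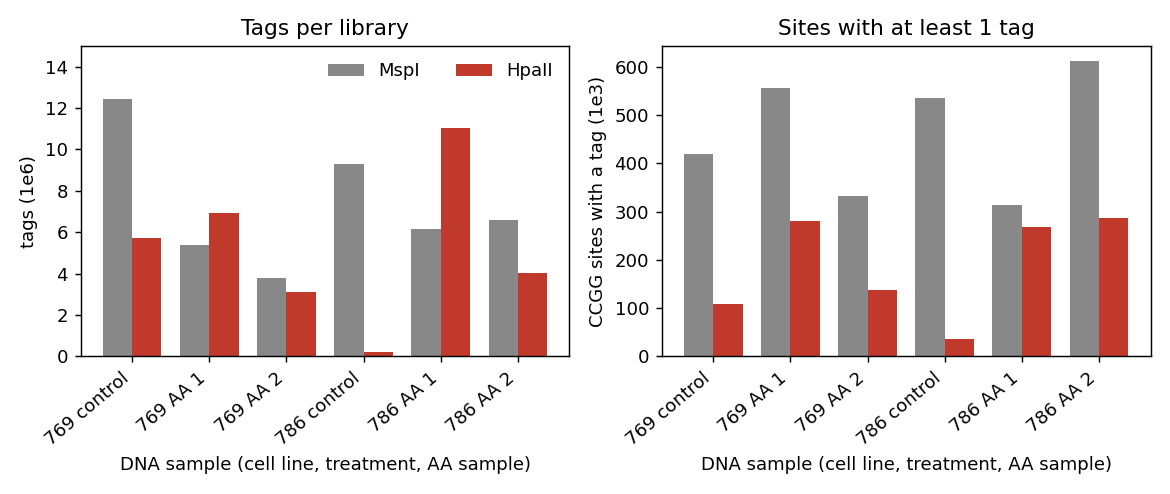
Bars show the tags (left, in units of 1e6) and the CCGG sites with at least 1 tag (right, in units of 1e3) of each MspI library (grey) and HpaII library (red), 1 library per bar, for the 6 DNA samples. The 786 control HpaII library holds 189704 tags at 35497 sites, below the other HpaII libraries.

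The first comparison asked whether AA treatment changed where in the genome HpaII cut. In 769, HpaII tags of the AA-treated samples lay more often at isolated CCGG sites and less often in CCGG-dense stretches than those of the control. At isolated sites, with 1 to 2 reference CCGG sites in a 1 kb window, the HpaII tag share divided by the MspI tag share was 0.159 in the 769 control and 0.335 ± 0.011 (SD, n = 2) in the AA samples, 2.11 times the control. At sites in dense stretches, with 16 or more, the ratio was 3.95 in the control. With AA it was 2.59 ± 0.108 (SD, n = 2), 0.656 times the control. Isolated sites took 3.71% of the control HpaII tags (95% Wilson interval 3.70% to 3.73%), 7.74% of those in AA replicate 1 and 7.58% of those in AA replicate 2. Their MspI tag shares were 23.4%, 23.7% and 22.1% in the same 3 DNA samples.

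In 786 the ratio at isolated sites was already higher in the control, at 0.499, and was 0.554 ± 0.0725 (SD, n = 2) with AA, 1.11 times the control. In dense stretches it was 2.64 in the 786 control and 2.36 ± 0.143 (SD, n = 2) with AA, 0.894 times the control. The ratio at isolated sites divided by that in dense stretches, the sparse-to-dense ratio, was 0.0403 in the 769 control, 0.123 in AA replicate 1 and 0.136 in AA replicate 2. The geometric mean of the 2 AA values was 3.21 times the control in 769, and 1.24 times the control in 786, where the control stood at 0.189 and the AA samples at 0.268 and 0.204. By chromosome, both 769 AA samples exceeded the control on 22 of 23 chromosomes, with chromosome 21 as the exception. Both 786 AA samples exceeded theirs on 18 of 23 chromosomes and both lay below it on 3. The AA effect over both lines had a two-sided p of 0.111 in an exact permutation of the treatment labels within lines, the smallest p that its 9 arrangements allow, so this design cannot reach 0.05. The difference between the lines had a two-sided p of 0.33 in the same exact permutation. Scaling to mitochondrial tags in place of library totals multiplies all classes of a sample by 1 factor, so it leaves the sparse-to-dense ratio the same. The classes themselves then stand lower with AA in 769, at 0.104 and 0.113 against 0.418 in the control for isolated sites and 0.847 and 0.83 against 10.4 in dense stretches. This follows from the low mitochondrial HpaII over MspI ratio of that control, so the 2.11 times above holds for library totals. The classes of CCGG density were set after the data were seen. When sites with a tag were counted in place of tags, the 786 fold was 2.05, and among sites with at least 10 MspI tags in all 6 MspI libraries it was 0.984.

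**Figure D2:**
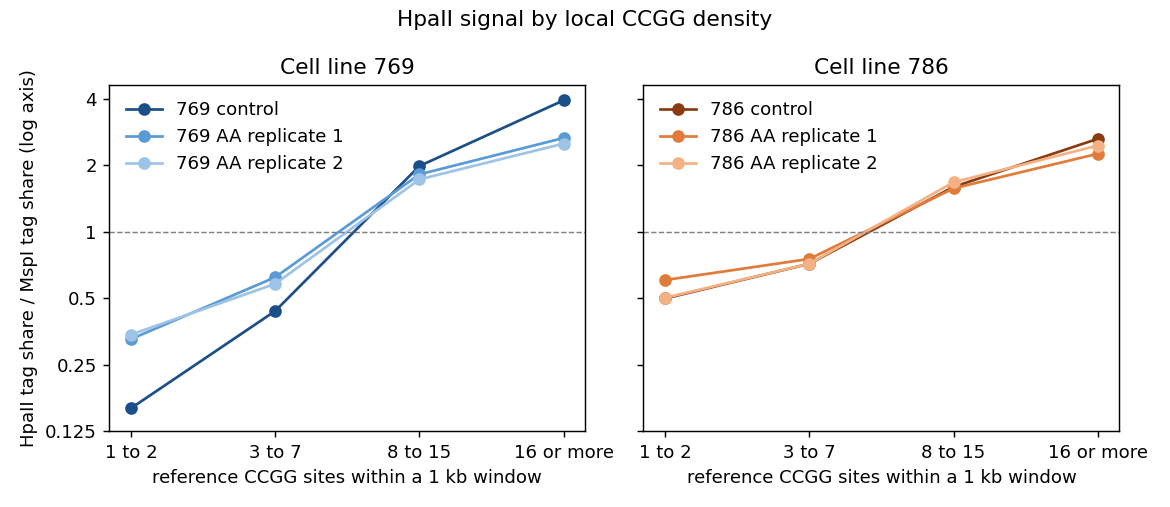
Points show, for each of the 6 DNA samples, the HpaII tag share divided by the MspI tag share (vertical, log axis) in 4 classes of reference CCGG sites within a 1 kb window (horizontal), 1 value per sample and class. At 1 to 2 sites the 769 control lies at 0.159 and its AA samples at 0.327 and 0.342, while the 786 samples lie between 0.499 and 0.605.

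The second comparison tested AA against control in 100 kb bins, both lines together. Over the 15623 bins tested the median log2 fold change was 0.59, so the bins as a whole lay above 0. It was 0.048 among the 4384 bins with at least 10 HpaII tags in every library. Of the 15623 bins, 48 changed in edgeR's quasi-likelihood test at an adjusted p under 0.05. Of these 48, 46 were higher and 2 lower in HpaII signal relative to MspI with AA, counts that sit on this offset. Of the same 48, 46 were also called for 769 in the fit by line, described below. The naming rule required each bin to be higher in 4 of 4 AA samples than in the control of its line. The 5 with the largest rise had 0 HpaII tags in both controls. Their folds are therefore lower bounds against a floor of 3 tags per library. On chromosome 19, the bin from 29800001 to 29900000 (hg19) held 419 and 146 HpaII tags in the 769 AA samples and 505 and 126 in the 786 AA samples, at least 16.1-fold higher over both lines (edgeR adjusted p = 0.041). The bin on chromosome 15 from 81400001 to 81500000 held 167, 110, 808 and 172 HpaII tags in the 4 AA samples and was at least 22.1-fold higher (edgeR adjusted p = 0.047). The bins on chromosome 9 from 134500001 to 134600000, chromosome 17 from 55700001 to 55800000 and chromosome 18 from 74300001 to 74400000 were at least 9.92-fold, 9.04-fold and 12.6-fold higher. The bounds came mostly from 769, where they ran from 75.9-fold to 153-fold over these 5 bins. In 786, where 3 tags are a large share of a shallow control, they ran from 1.05-fold to 4.27-fold. Without the 769 control the AA term rests on 786 alone, and none of the 5 passed there. None passed without 769 AA replicate 1 (edgeR adjusted p of 0.172 in each) or without 769 AA replicate 2 (0.132 to 0.155). They also did not pass with libraries thinned to the smallest (0.227 to 0.298), with HpaII alone (0.091 to 0.12) or without a cell line term (0.0569 to 0.156).

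The 2 bins that fell lay on chromosome 5 from 14600001 to 14700000 and on chromosome 9 from 140200001 to 140300000. Their log2 fold changes were -2.16 ± 0.41 (SE) and -1.97 ± 0.36 (SE), at edgeR adjusted p of 0.047 and 0.046. Each was lower in 4 of 4 AA samples, as the naming rule required. In the chromosome 5 bin the HpaII tag share over the MspI tag share was 6.92 in the 769 control against 2.44 and 2.96 with AA, and 21.2 in the 786 control against 2.84 and 2.35. In the chromosome 9 bin it was 0.25 in the 769 control against 0.13 in both AA samples, and 3.14 in the 786 control against 0.39 in both. On chromosome 7, 3 bins had the next smallest p in that direction and did not pass: from 49800001 to 49900000 (log2 fold change -3.12), from 156800001 to 156900000 (-1.53) and from 98900001 to 99000000 (-1.55), at edgeR adjusted p of 0.057, 0.063 and 0.083. The 2 bins that fell no longer passed without 769 AA replicate 1 (edgeR adjusted p of 0.178 and 0.172) or 769 AA replicate 2 (0.155 in both). Without the 786 control the AA term rests on 769 alone, and their log2 fold changes were -1.43 and -1.07. Without the 769 control the term rests on 786 alone, and they were -2.97 and -2.94. Both falls were thus larger in 786, where they were measured against the shallow control. The 2 bins passed with libraries thinned to the smallest, but not with HpaII alone (edgeR adjusted p of 0.0908 in both). They also did not pass without a cell line term (0.213 and 0.529). The chromosome 5 bin did not pass with at least 10 HpaII tags in every library (0.0536). The 3 bins on chromosome 7 passed without 786 AA replicate 1 and without 786 AA replicate 2. They did not pass without 769 AA replicate 1 or without 769 AA replicate 2. In 769 alone, as fitted without the 786 control, the log2 fold changes of these 3 bins were -1.48, -1.03 and -1.83. In 786 alone, as fitted without the 769 control, they were -4.88, -2.11 and -1.32.

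The count over both lines depended on single samples. In edgeR's test it was 0 without 769 AA replicate 1 (1557 at an unadjusted p under 0.05) and without 769 AA replicate 2 (2121 unadjusted). The count was 207 without 786 AA replicate 1 and 216 without 786 AA replicate 2. Without the control of either line no count over both lines exists, because the AA term then rests on the other line alone. With libraries thinned to the smallest the count over both lines was 17 of 11135 bins tested, with 6 higher and 11 lower.

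Fitted by line, 582 bins were called between the AA samples and the control in 769 (559 higher, 23 lower with AA) and 60 bins in 786 (19 higher, 41 lower), and 154 bins were called for a difference of this AA contrast between the lines (edgeR, adjusted p under 0.05 in each test). Each line has 1 control, so these calls do not separate AA from a property of that control library. Over all tested bins the median log2 fold change was 0.43 in 769, 0.99 in 786 and 0.79 for 786 minus 769. Among bins with at least 10 HpaII tags in every library these medians were -0.02, 0.11 and 0.11. In 26 of the 154 the contrast was greater in 786 and in 128 it was greater in 769, against the direction of the median bin. With libraries thinned to the smallest this balance turned, with 86 greater in 786 and 67 in 769, and without a low count filter it was 297 against 344. The 769 bins that rose held a median of 1 HpaII tag in the 769 control, 218 in AA replicate 1 and 89 in AA replicate 2, and 211 of the 559 had 0 in the control. Among bins with at least 10 HpaII tags in every library, chosen after their values were seen, the 3 rises in 769 with the smallest p all lay on chromosome 9. In the bin from 133200001 to 133300000 the HpaII tag share over the MspI tag share was 0.02 in the 769 control and 0.43 and 0.31 with AA, a log2 fold change of 4.37 ± 0.48 (SE, edgeR adjusted p = 0.00054), higher in 2 of 2 AA samples. The bins from 137700001 to 137800000 and from 137100001 to 137200000 had log2 fold changes of 3.36 ± 0.37 (SE) and 3.62 ± 0.42 (SE). Among the falls in 769, the bin on chromosome 2 from 2600001 to 2700000 had a ratio of 2.28 in the control against 0.29 and 0.40 with AA, and that on chromosome 7 from 98900001 to 99000000 had 3.50 against 1.15 and 0.91. The bins on chromosome 9 from 137700001 and 137100001 and that on chromosome 2 did not pass after thinning to the smallest library (edgeR adjusted p of 0.0978, 0.0878 and 0.0595).

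In 786 the 3 falls with the smallest p, chosen in the same way, lay on chromosome 2 from 202300001 to 202400000, chromosome 7 from 49800001 to 49900000 and chromosome 17 from 45500001 to 45600000. Their ratios were 129, 12.2 and 64.6 in the 786 control, against 0.38 to 3.87 in the 786 AA samples. These control values rest on 274, 147 and 275 HpaII tags. Over the 41 bins that fell a median of 94.5% of the control tags lay at a single CCGG site, against 21.2% and 18.1% in the AA samples. With libraries thinned to the smallest, of 11135 bins tested the 769 count was 40 and the 786 count was 230, with 150 higher and 80 lower. Without 769 AA replicate 2 the 769 count was 970. Without 769 AA replicate 1, 786 AA replicate 1 or 786 AA replicate 2 the 786 count was 38, 131 and 174. The count of bins that differed between the lines was 94, 317 and 364 without those same 3 samples.

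A score of site hypomethylation, the angle of the HpaII over the MspI tag share scaled from 0 (no HpaII) to 100, was taken over 17290 sites with at least 10 MspI tags in all 6 MspI libraries. Its median was 0 in both controls and in 769 AA replicate 2, 1.97 in 769 AA replicate 1, 4.04 in 786 AA replicate 1 and 5.84 in 786 AA replicate 2. Its mean was 11.3 in the 769 control against 24.3 and 16.9 with AA, and 11.9 in the 786 control against 26.2 and 27.6. The share of these sites with any HpaII tag was also higher with AA. It was 26.1% in the 769 control against 67.7% and 36.2%, and 16.35% in the 786 control against 54.5% and 53.9%. Over both lines the AA effect had a two-sided p of 0.222 for the median and 0.111 for the mean in exact permutations, of which 0.111 is the smallest possible. With libraries thinned to the smallest, the median was 0 in all 6 samples. The mean was then 9.74 in the 769 control against 21 and 15 with AA and 11.8 in the 786 control against 22.2 and 23. The share of sites with an HpaII tag was then 13.8% against 31.4% and 22.4% in 769, and 16% against 34.6% and 33.9% in 786. Thinning evens tags but not library complexity, so the score does not separate AA from a difference in complexity.

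The third comparison set the lines against each other. Of the 15623 bins, 147 differed between 786 and 769 in edgeR's test at an adjusted p under 0.05, with 127 higher and 20 lower in HpaII signal relative to MspI in 786. The 5 largest rises had 0 HpaII tags in all 3 samples of 769, and no value of one line overlapped the other, as the naming rule required. Against a floor of 3 tags per library, 786 was at least 41.9-fold higher on chromosome 13 from 52800001 to 52900000, 66.7-fold on chromosome 7 from 29300001 to 29400000, 80.3-fold on chromosome 11 from 50200001 to 50300000, 64.8-fold on chromosome 5 from 26400001 to 26500000 and 75.6-fold on chromosome 18 from 22400001 to 22500000. In the chromosome 5 bin the 786 samples held 10, 1144 and 329 HpaII tags and the 769 samples 0, beside 93 to 159 MspI tags (edgeR adjusted p = 0.0056). In the chromosome 13 bin the ratio was 146 in the shallow 786 control against 1.37 and 1.13 in the 786 AA samples, so the bound rests largely on that control. It did not pass without the 786 control (edgeR adjusted p = 0.397) or the 769 control (0.104). None of the 5 passed without 769 AA replicate 2 (0.0635 to 0.129), and the chromosome 18 bin did not pass without 769 AA replicate 1 (0.0504). The bins on chromosomes 7, 11, 5 and 18 did not pass after thinning to the smallest library (0.0539 to 0.0748), and the chromosome 13 bin was not tested there. Without a treatment term those on chromosomes 13, 7 and 18 did not pass (0.195, 0.0647 and 0.0604).

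In the other direction, 3 bins had 0 HpaII tags in all 3 samples of 786. They were at least 26.6-fold lower in 786 on chromosome 4 from 40800001 to 40900000, 22.5-fold on chromosome 1 from 232900001 to 233000000 and 13.1-fold on chromosome 1 from 243600001 to 243700000. On chromosome 7 from 127600001 to 127700000 the 769 samples held 440, 178 and 120 HpaII tags and the 786 samples 1 in all, a ratio of 992 (95% counting interval 178 to 39192). On chromosome 4 from 1900001 to 2000000 they held 28, 109 and 29 against 1, a ratio of 132 (95% counting interval 23.7 to 5209). These 2 ratios pool the tags of a line, so the deep 786 AA libraries weigh most, and they are not on the scale of the bounds above. On that scale, with 3 tags set in each 786 library, the values are 37.3 and 4.77. None of these 5 bins passed without 769 AA replicate 2 (edgeR adjusted p from 0.0635 to 0.159). After thinning to the smallest library the 2 bins on chromosome 1 did not pass (0.0671 and 0.113) and the second chromosome 4 bin was not tested, and with HpaII alone that bin did not pass (0.109).

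Among deeply covered bins, 2 were chosen after their values were seen. The bin on chromosome 1 from 161400001 to 161500000 had HpaII over MspI share ratios of 2.36, 1.72 and 1.61 in 769 and 0.35, 0.29 and 0.45 in 786 (log2 fold change -2.46 ± 0.20 SE, edgeR adjusted p = 0.00017). The bin on chromosome 22 from 49000001 to 49100000 had 0.37, 0.28 and 0.20 in 769 and 1.45, 1.55 and 1.45 in 786 (2.36 ± 0.32 SE, edgeR adjusted p = 0.0056). Without 769 AA replicate 2 the first still passed and the second did not (edgeR adjusted p of 0.0077 and 0.0905). On the unplaced contig that carries ribosomal RNA genes, the HpaII tag share over the MspI tag share was 2.05 ± 0.44 (SD, n = 3) in 769 and 0.831 ± 0.13 (SD, n = 3) in 786, with no overlap. The sparse-to-dense ratio was 0.0998 ± 0.052 (SD, n = 3) in 769 and 0.22 ± 0.0418 (SD, n = 3) in 786, again with no overlap. Each n = 3 pools the control and the 2 AA samples of a line, so these SDs include any difference with treatment. In 769 the ribosomal ratio was 2.56 in the control against 1.84 and 1.75 with AA. The lines overlapped when sites with a tag were counted (769 up to 0.232, 786 from 0.137) and among sites with at least 10 MspI tags in all 6 MspI libraries (769 up to 0.444, 786 from 0.435). The ribosomal ratio and the sparse-to-dense ratio over all sites each had a two-sided exact permutation p of 0.1, the smallest that 3 samples against 3 allow, so they cannot reach 0.05. The count of 147 bins was 3 without 769 AA replicate 2, with 0 higher and 3 lower in 786. These 3 are too few to read a balance from. The count was 289 (243 higher, 46 lower) without 786 AA replicate 1 and 374 (308 higher, 66 lower) without 786 AA replicate 2.

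The MspI libraries, which do not read methylation, give the MspI side of the background of the AA comparison. In them 0 of 15623 bins passed edgeR's test of AA against control at an adjusted p under 0.05. An unadjusted p under 0.05 was found in 566, and DESeq2 called 3 bins. Every tested bin held at least 10 MspI tags in each MspI library. By contrast, 3691 tested bins had 0 HpaII tags in the 769 control and 5784 in the 786 control. The MspI fit thus could not show false calls that arise in the HpaII libraries.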

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

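The tests of explanations for the shift in 769 and the splits of the samples between lines were written down after their values were seen; the 2 tests on the called bins, of single sites behind the 41 falls in 786 and the 559 rises in 769, were set beforehand, except the comparison of these falls with bins of matched tag counts.

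The contrast of AA samples with the control differed between the lines in 154 bins of 100 kb by edgeR's test of the difference itself, with 26 greater in 786 and 128 greater in 769. With 1 control per line this does not separate AA from a property of either control library. The balance turned with libraries thinned to the smallest, with 86 greater in 786 and 67 in 769. Mitochondrial sites, which none of the comparisons used, had an HpaII tag share over the MspI tag share of 3.02 and 2.83 in the 769 AA samples against 0.364 in the 769 control. In 786 it was 4.35 in AA replicate 1, 1.98 in AA replicate 2 and 2.63 in the control.

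The pattern in 769 is that HpaII tags of both AA samples lay more often at isolated CCGG sites than those of the control. A chance draw of few molecules in the control is argued against by its spread over the genome, since both AA samples exceeded the control on 22 of 23 chromosomes. 786 DNA in the AA samples is argued against by a mitochondrial site with a tag in every 786 library and none in the 769 control, where the 769 AA HpaII libraries held 0 tags, which allows a 786 share of up to 2.22% against the 42.5% and 46.4% the shift would need. MspI tags carried into the AA HpaII libraries, as the whole cause, would move every class towards 1 by a single share, but dense stretches need 43.5% and 48.7% of such tags and isolated sites 20% and 21.8%, at least 2.18 times apart. Part of the shift is not excluded this way. In the 769 AA samples the odds ratio of isolated sites with their own MspI library was 1.01 and 1.09 times that with the others of the line. In the 769 control it was 0.923 times. In 786, outside this pattern, it was 1.07 times in the control and 0.996 and 1.02 times with AA, so these values do not settle it. A systematic effect of low complexity in the control stays open, because the 786 control alone lists under 1.5 times as many sites outside this pattern, and its ratio of 4.69 times that of the 769 control belongs to another line. What also stays open is a bias of the single 769 control HpaII library, since its mitochondrial ratio of 0.364 lies far below the range of 1.98 to 4.35 in the other 5 samples, and an effect of AA, which this design confounds with that library.

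The 559 rises in 769 may reflect single molecules amplified in the AA libraries. Both AA libraries had the same top site in 30.5% of 548 such bins with enough tags, against 7.75% if top sites were drawn among the listed ones. More than 2 times the expected share was to count against single molecules, but the other bins also exceed it, at 21.8% against 6.50%, so this bound does not tell these bins from bins in general and the question stays open. The low tag count of the control, a median of 1 per bin, stays open for these bins too, as part of the bias above.

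The 41 falls in 786 may come from few amplified molecules in the shallow 786 control HpaII library. A median of 94.5% of its tags in these bins lay at a single site, against 21.2% and 18.1% in the AA libraries, as that explanation needs. The same share in the 786 control was 14.7% in other bins with tag counts within 1.5 times (median over the 41 bins), and 62.5% over all other bins with a tag, many of which hold few tags. A loss of HpaII cutting with AA in these bins was not tested apart from it.

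For the difference between lines, 147 bins were called for the real split of the 6 DNA samples and at most 0 for the others, and 1 of the 10 splits, the real one, gave as many. With 10 splits the share cannot fall under 0.05.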

How the results depend on the processing

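The settings for the 100 kb bins over both lines and between lines, and for the median site score apart from leaving out samples, were fixed before the data were examined; leaving out samples for that score, and the settings of the fits by line, of their difference, of the MspI background, of the mean score and of the sparse-to-dense ratio were added after the data were seen. The causes of the changes were not tested.

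Library totals without TMM left the counts of bins of all 6 tests within 1.5 times their values, as did TMM over all 12 libraries in the 5 tests it was run on, MspI alone being the exception. DESeq2 called 566 bins for AA over both lines, 1348 between lines, 2204 for AA in 769, 155 in 786, 955 for the difference between the lines and 3 in MspI alone. Without a low count filter these counts were 369, 642, 1089, 382, 641 and 1. With at least 10 HpaII tags in every library, 9 bins were called over both lines, 196 in 769 and 79 for the difference. Thinned to the smallest library, 11135 bins were tested, of which 17 were called over both lines, 40 in 769 and 230 in 786. HpaII alone gave 0 over both lines (2060 at an unadjusted p under 0.05), 339 between lines, 1193 in 769, 228 in 786 and 674 for the difference. In bins of 1 Mb, of which 2877 were tested, the counts were 0 over both lines (372 unadjusted), 84 between lines, 103 in 769 and 101 for the difference. Without a cell line term 0 bins were called over both lines (1500 unadjusted), and without a treatment term 57 between lines.

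With the replicate number as a block, 268 bins were called over both lines and 494 between lines. The numbers are shared by only 2 pairs, and the deviations of same-numbered AA samples had a correlation of 0.02 over 4384 bins, so the pairing rests on the number alone.

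Leaving out each DNA sample in turn gave 0 to 554 bins over both lines, 3 to 374 between lines, 554 to 970 in 769, 38 to 174 in 786, 94 to 364 for the difference and 0 to 4 in MspI alone. No count by line was made without that line's own control, and for the difference only AA samples were left out. The 554 over both lines is without the 786 control, where the AA term rests on 769 alone. For the folds and scores, too, only AA samples were left out. The sparse-to-dense fold was then 3.05 to 3.38 in 769 and 1.08 to 1.42 in 786, and the 769 fold over the 786 fold was 2.27 to 2.97. The mean score difference was 5.60 to 13.1 in 769 and 14.4 to 15.8 in 786, and the median difference 0 to 1.97 and 4.04 to 5.84. The ranges of the folds and scores therefore do not test the single control of a line.

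The 769 sparse-to-dense fold of 3.21 was 2.75 over sites with whole counts, 2.64 with counts capped at 20 tags per site and also 2.64 by sites with a tag, 2.59 with dense sites set at 8 or more, 2.82 in a window of 2 kb and 4.81 at sites with 10 MspI tags in all 6 libraries. The 786 fold of 1.24 was 2.05 by sites with a tag and, in the other direction, 0.984 at sites with 10 MspI tags in all 6 libraries. The 769 fold over the 786 fold was 2.60, and 1.78, 1.29 and 4.89 with the cap, by sites and at those MspI-covered sites. The mean score difference in 786 was 15.1, and 13.5 with at least 20 MspI tags, 16.4 with at least 5 and 10.8 after thinning, where the median difference was 0.

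Over the named bins and their settings, 390 values kept direction and side of the threshold, and 72 kept direction and no longer passed. Another 19, of bins that had not passed, did so, and none turned. The bins were named for their direction or a small p in these data, so they had little room to turn. Settings in which a bin was not tested are not counted. The promoter and gene list settings, and the promoter share of tags, were not run because no annotation of this build was used here. The depth of the 786 control HpaII library, with a median of 4 tags per tested bin and 0 in 5784 of 15623, limits every AA effect in 786.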

Other observations

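The MspI libraries, read as DNA copy number, separated the lines over long stretches of chromosomes. The segments were defined after the data were seen. Of 2708 autosomal bins of 1 Mb, 655 differed between 786 and 769 in edgeR's test at an adjusted p under 0.05, and 481 of these fell into 18 segments, 7 higher and 11 lower in 786. The segments join bins already called between the lines, so their separation follows from this choice. On chromosome 1 from 1 to 30 Mb, 786 had 3.69% ± 0.0783 of its MspI tags (SD, n = 3) and 769 had 1.87% ± 0.0697 (SD, n = 3), 1.97 times as many in 786. The short arm of chromosome 3 from 3 to 67 Mb, the arm most often lost in clear cell renal carcinoma, was 1.61 times as high in 786 as in 769. Chromosome 5 was 1.62 times as high in 786 from 0 to 45 Mb and 0.601 times as high from 50 to 82 Mb. Chromosome 7 from 55 to 159 Mb was 1.42 times as high, chromosome 11 from 93 to 135 Mb 1.67 times and chromosome 20 from 30 to 63 Mb 1.23 times. Chromosome 8 from 0 to 44 Mb was 0.548 times as high in 786, with 0.780% ± 0.017 of the MspI tags (SD, n = 3) against 1.42% ± 0.0485 (SD, n = 3). The end of chromosome 4 from 178 to 191 Mb was 0.378 times as high.

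These values are shares of a library, so they give copy number relative to the rest of each genome. AA against control in the same 1 Mb MspI fit gave 0 of 2855 bins at an adjusted p under 0.05 and 105 at an unadjusted p under 0.05 (edgeR; no other tool was run on it).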
